A study of Homo sapiens with 6 samples.

How the data were processed

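RNA from NCI-H1299, an established human line of non-small-cell lung carcinoma that lacks functional p53, was measured on Affymetrix PrimeView arrays, which read labelled RNA near the 3′ end of each transcript with sets of short probes. Per the labels' protocols, cells in logarithmic growth were infected with 20 µL of a lentivirus carrying either a control short hairpin RNA (shCtrl) or one against RPL35A (shRPL35A), in medium with 10% fetal bovine serum at 37 °C and 5% CO2. Total RNA was extracted with Trizol and 6 µg of it was turned into biotin-labelled RNA, per the labels' protocols. Each of the 6 samples went on its own array with 1 colour, 3 arrays per group, and the groups were taken from the sample titles. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The time between infection and harvest and the hairpin's target sequence are not given in the sources used here.

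The values used are the authors' deposited table of probe set signals, which the values show to be on a log2 scale (from about 2 to 14) with closely matching medians and quartiles on all arrays. The summary method, the normalization and the software behind that table are not given in the sources used here. Per the series' design text, the authors called genes with the Welch form of the unpaired test on 2 means, with Benjamini-Hochberg adjustment, a fold of at least 1.3 and an FDR under 0.05, and then ran a commercial pathway tool, which was not run here. The table holds 47481 probe sets, and all 6 columns of values were matched to a sample (0 were unmatched). The platform annotation gave 43976 probe sets exactly 1 gene symbol, 1558 several and 1947 none. Of those with 1 symbol, 43954 matched the RefSeq gene table by gene ID, and 0 symbols needed updating. No genome build is named for the files, so no coordinates are given.

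Gene symbols stood for 17534 genes. Where several probe sets carried a gene's symbol (11527 genes), the one with the highest mean over the 6 arrays stood for the gene, and the text gives the others of a named changed gene where at least 1 of them was not called the same way. Probe sets with the suffix s or x match several transcripts, so values from them may be shared between near-identical genes. Probe sets with no or several symbols were left out of the gene-level tests. No filter on low values was applied. Arrays give no counts, so precision is limited by the number of arrays and by signal over background.

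The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided, Benjamini-Hochberg over all 17534 genes), as shRPL35A minus shCtrl. A gene was called changed at an adjusted p under 0.05 with a fold of at least 1.3 either way, the threshold the series states. limma replaced the series' own test because 3 against 3 arrays leave few degrees of freedom for a separate spread per gene, and the series' test was run as an alternative. Exact permutation tests on 3 against 3 arrays cannot go below p = 0.10.

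Gene lists were tested with camera in limma, with its preset inter-gene correlation of 0.01 and Benjamini-Hochberg over lists, and called at an adjusted p under 0.05. There were 41 lists, which covered ribosomal proteins, ribosome production, translation, the cell cycle, DNA repair, stress responses, metabolism, signalling, adhesion, cell death and markers of other cell types. A list needed 8 measured members, which 40 lists had; the list of snoRNA host genes had 2 (SNHG12 and EPB41L4A-AS1, neither called) and was not tested. RPL35A was in no list. For each list, members called over all genes and adjusted over the list alone were counted. camera with an estimated correlation and fry were run beside it. A list's score on an array was the mean of its members, and differences between lists were compared with exact permutation tests.

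The 41 lists, the tests of genes and lists, the alternatives listed below and the rule for named genes were set before the data were examined. A further alternative that leaves out probe sets of suffix s or x, the comparisons of list scores between lists, and the further lists and tests of explanations were set after a first look at the data. The rule took RPL35A; the 12 largest rises and 12 largest falls among called genes at or above the median signal whose 3 arrays of one group all lay above those of the other; up to 4 called members per called list in its direction; and up to 2 called members of every other list. Symbols of uncharacterised reading frames or loci, XIST and Y-linked genes were counted and not named. The rule gave 100 genes, of which the text prints a part. Named outside the rule, and chosen after their values were seen, were ABCA1, AMOTL1, APOC1, ASNS, ASPM, ATG3, AURKB, CCNB1, CCNE1, CDH1, CDK1, CDKN1A, ESPL1, GABARAPL2, GBP1, IFITM3, LPCAT3, MAP1LC3B, MDM2, MYLIP, NR1H3, RPL11, RPL13, RPL27A, SDF2L1, TM7SF2, the snoRNA host genes SNHG12 and EPB41L4A-AS1 and the neighbours of RPL35A.

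On simulated arrays with the means and spreads of this comparison and 17534 genes, the test recovered 27 of 50 genes set at a fold of 1.3 (46 of 50 passed with no fold threshold) and 50 of 50 at each of 1.5, 2 and 4; 1 unchanged gene was called. In the simulated list test, the 1 list that had been shifted was called and 0 of the others were. The run was set to stop at any other outcome. Genes were drawn independently in both simulations, so they cannot show how often correlated members give false calls. The alternatives were the series' own test, limma with trend and robust settings, array weights, a block for the replicate number, averaging of the shCtrl arrays that share a source name, quantile normalization, centring on the median or on housekeeping genes, a filter on the dimmest genes, other choices of probe set, other fold thresholds and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.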

Results

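Expression was measured in NCI-H1299 lung carcinoma cells infected with a control hairpin (shCtrl, 3 arrays) or with a hairpin against RPL35A (shRPL35A, 3 arrays). RPL35A encodes a protein of the large ribosomal subunit. Each array gave a log2 signal for 47481 probe sets, with array medians from 6.33 to 6.36. The question was which transcripts differ between cells with and without the knockdown. Within groups, the SD of the difference between arrays over genes was 0.107 to 0.118, against 0.297 to 0.305 between groups. shCtrl arrays 2 and 3 share a source name in the labels; their difference had an SD of 0.109, within the range of the other pairs, and they were kept as 2 replicates. The first principal component held 83.3% of the variance and separated the groups.

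RPL35A itself was lower on every shRPL35A array. The brightest probe set with its symbol alone read 11.03, 11.07 and 11.06 on shCtrl arrays 1, 2 and 3, and 9.12, 9.10 and 9.03 on shRPL35A arrays 1, 2 and 3. The mean went from 11.05 ± 0.018 to 9.09 ± 0.045 (SD, n = 3), a log2 fold change of −1.97 (SE 0.035, adjusted p = 1.77e-06 by limma), which left 25.6% of the control signal. Its other probe sets had log2 fold changes of −2.43 and −2.71, and were dim in shRPL35A, at 4.59 and 5.27, so the sizes of these falls are uncertain. A brighter probe set shared by RPL35A and another gene went from 13.89 ± 0.0060 to 11.36 ± 0.036 (SD, n = 3), a log2 fold change of −2.53 that left 17.3%. RPL35A ranked 2 of 17534 genes by p. No nearby gene was called: LMLN, the next gene in the gene table's order, had a log2 fold change of 0.23, and DRC9, the nearest measured gene on the other side, 0.31.

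**Figure D1:**
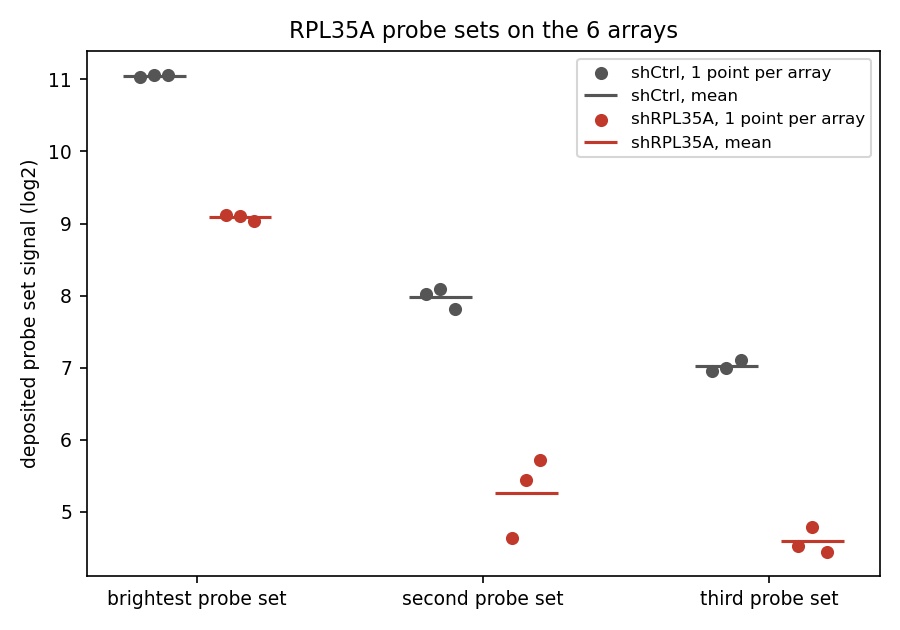
Deposited log2 signal (vertical axis) of the 3 probe sets that carry the RPL35A symbol alone, with 1 point per array and a line at each group's mean. All 3 shRPL35A arrays lie below all 3 shCtrl arrays in each probe set, with log2 fold changes of −1.97, −2.71 and −2.43.

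Genes of mitosis fell together in shRPL35A, and a secreted protease, protease inhibitors and a lipid carrier stood among the largest rises of genes at or above the median signal. MMP1, an interstitial collagenase, rose 11.04-fold, from 7.41 ± 0.12 to 10.87 ± 0.085 (SD, n = 3; log2 fold change 3.46, SE 0.072, adjusted p = 2.00e-06), and its other probe set rose by 3.60. GGCT, an enzyme of glutathione breakdown, fell 5.13-fold, from 9.76 ± 0.0084 to 7.40 ± 0.035 (log2 fold change −2.36, SE 0.032, adjusted p = 5.30e-07). In all, 2496 of 17534 genes were called changed (14.2%), 1480 higher and 1016 lower. Only 180 changed at least 2-fold, 83 higher and 97 lower. The 3 arrays of one group all lay above those of the other for 2495 of the 2496, and for 9150 of all genes, where chance gives 10%. The split by direction depended on scaling: higher genes made up 59.3% of calls on the deposited values, but 45.0% (1122 higher, 1370 lower) with arrays centred on their medians and 45.9% (1143 higher, 1347 lower) with arrays centred on housekeeping genes. Of the 1846 called genes with another probe set, 1497 had every probe set in the same direction and 26 had one called the opposite way.

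Among genes at or above the median signal, the largest rises after MMP1 included KLC3, a kinesin light chain (1.60, SE 0.049), and RAB15, a small GTPase of endosomes (1.58, SE 0.040). Inhibitors of serine proteases were among them, with SERPINE2 at 1.54 (SE 0.034; its other 5 probe sets between 0.17 and 1.83) and SERPINI1, neuroserpin, at 1.37 (SE 0.050). IGFBP6, a secreted binding protein of insulin-like growth factors, rose by 1.44, and APOE, a lipid carrier of lipoproteins, rose by 1.43 from an already bright 10.65 ± 0.036 (SD, n = 3). The only probe set of APOE has the suffix x, so its signal may be shared. The transcriptional co-regulator CITED1 rose by 1.35. KCTD20, DENND4A and IER3IP1 rose by 1.48, 1.42 and 1.36, with smaller rises in their other probe sets (0.64 to 1.08, 0.24 to 0.81 and 0.77). NATD1 rose by 1.30 in its brightest probe set, while its other probe set stood at −0.01.

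Among genes at or above the median signal, the largest falls after GGCT and RPL35A were IL12A, a subunit of interleukin 12 (−1.82, SE 0.038), and KIF20A, a kinesin of cytokinesis (−1.78, SE 0.050). ZIC5, a zinc finger transcription factor, fell by 1.76 (0.73 in its other probe set). FOXM1, a transcription factor that drives mitotic genes, fell by 1.65, and SPC25, a kinetochore protein, fell by 1.51. SKP2, the ubiquitin ligase subunit that marks CDKN1B for breakdown, fell by 1.46, and CCNA1, a cyclin, by 1.46. MYDGF, a secreted growth factor, fell by 1.45, and NHLRC3 by 1.43. RRP7A, a factor of small subunit assembly, fell by 1.42 in its brightest probe set, while its 4 other probe sets, all dimmer, lay between −0.18 and 0.07. A probe set shared by RRP7A and another gene, at 7.86 in shCtrl, fell by 1.44 (SE 0.097, adjusted p = 4.18e-05 over all probe sets).

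**Figure D2:**
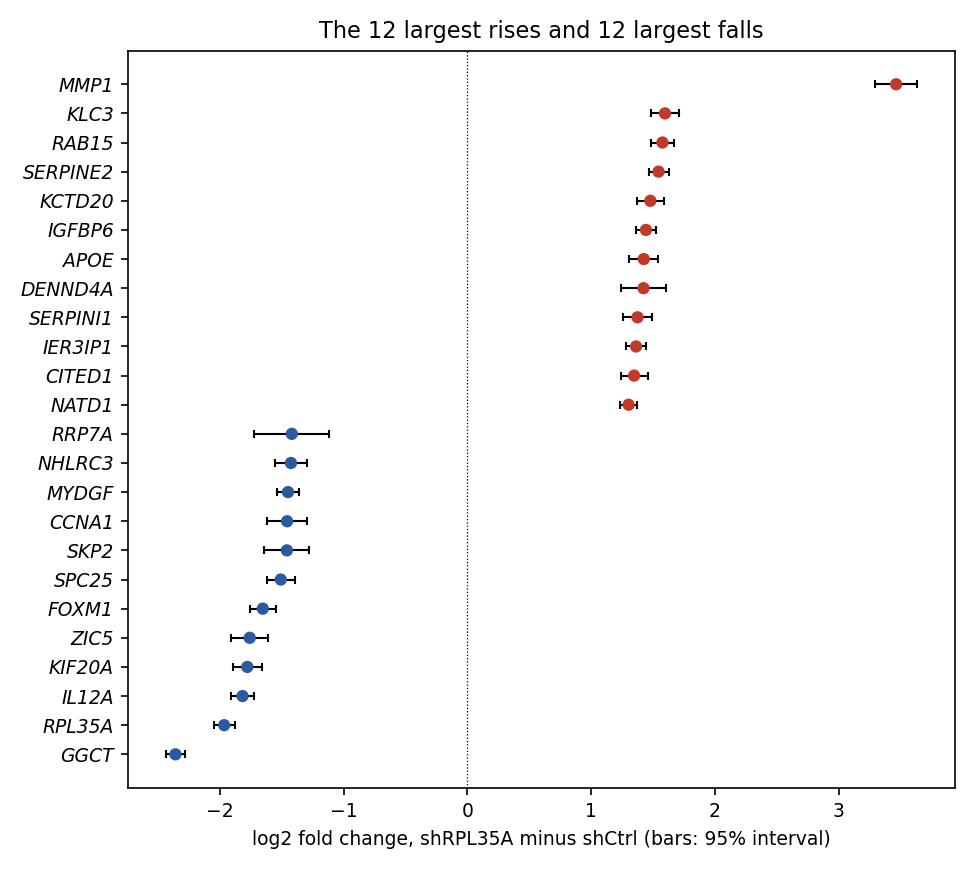
Log2 fold changes (horizontal axis, shRPL35A minus shCtrl) of the 12 largest rises and 12 largest falls among called genes at or above the median signal, with points for limma's estimates and bars for 95% intervals. MMP1, at 3.46, lies far above the next rise, KLC3 at 1.60, and RRP7A has the widest interval of the falls.

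Of 48 measured genes of mitosis and the G2/M phase, 39 fell, 0 rose and 9 did not pass, with the same counts adjusted over the list alone. Their median log2 fold change was −0.74 (adjusted p = 1.71e-26 by camera; adjusted p = 0.0122 with an estimated correlation). Beside KIF20A, FOXM1 and SPC25, the kinase NEK2 fell by 1.39, with all 6 of its other probe sets called lower. AURKB, CDK1 and CCNB1, a kinase of the chromosomal passenger complex, the kinase of mitotic entry and its cyclin, fell by 1.16, 1.02 and 0.65. ASPM, a spindle pole protein, was the 1 member above zero, at 0.10. This was the only list of the 40 tested whose call held with an estimated correlation.

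Of 45 measured genes of DNA replication and the G1/S step, 12 fell, 1 rose and 32 did not pass, and the counts adjusted over the list alone were the same. The median was −0.24 (adjusted p = 1.31e-06 by camera; adjusted p = 0.371 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell by 1.38 (0.88 in its other probe set), GINS4, part of the replicative helicase, by 0.69, and MCM10 by 0.66. The other 3 probe sets of GINS4 lay between −0.60 and −0.13. Without probe sets of suffix s or x, the GINS4 log2 fold change was −0.13 and did not pass. RFC3, a subunit of the clamp loader, fell by 0.64, but its other 3 probe sets lay between −0.69 and 0.26, and in their mean the RFC3 log2 fold change was −0.25, which did not pass. The member that rose was CCNE1, cyclin E1, by 0.82. On the scale of list means per array, the gap between the mitosis list and the replication list went from 1.21 ± 0.0049 to 0.66 ± 0.022 (SD, n = 3), a difference of −0.55 (exact permutation p = 0.1, the smallest possible, and the same after adjustment over 4 such comparisons).

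Of 30 measured genes of homologous recombination and the Fanconi pathway, 9 fell, 0 rose and 21 did not pass, with the same counts adjusted over the list alone. The median was −0.14 (adjusted p = 0.0228 by camera; adjusted p = 0.371 with an estimated correlation). UBE2T, the ubiquitin-conjugating enzyme of the Fanconi pathway, fell by 0.88, RAD54B by 0.59, FANCB by 0.57 and the nuclease EXO1 by 0.56. EXO1 did not pass in the methods' t-test, where the EXO1 log2 fold change had an adjusted p = 0.0620. Among cyclins, CDKs and inhibitors of G1, 2 of 17 rose and 2 fell (adjusted p = 0.884 by camera). CDKN1C, an inhibitor of CDKs, rose by 1.11, and MYC fell by 0.91.

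Of 40 measured large ribosomal subunit genes other than RPL35A, 16 had an unadjusted p under 0.05 by limma. The methods' t-test over all genes called 0 of the 40, as did limma over all genes or adjusted over the list alone. Their median was −0.056, with 14 lower and 0 higher at adjusted p alone and no fold threshold, and the list was called lower (adjusted p = 0.00146 by camera; adjusted p = 0.371 with an estimated correlation). RPL13 stood at −0.31, and RPL11 at 0.06, which turned to −0.01 with arrays centred on their medians. The only probe set with the RPL27A symbol alone, dim at 4.81 in shCtrl, stood at −0.34 and passed at −0.41 with that centring. It read far below its list's mean of 13.2 on shCtrl array 1, so it may not report the gene. Of the 40 probe sets, 36 carried the suffix s or x and may share signal with near-identical copies, so these values are uncertain. Of 23 small ribosomal subunit genes, 6 had an unadjusted p under 0.05 by limma. The methods' t-test over all genes called 0 of the 23, as did limma over all genes or adjusted over the list alone. Their median was −0.030, and the list did not pass on the deposited values (adjusted p = 0.0780 by camera), but it did with arrays centred on housekeeping genes (adjusted p = 0.00809) or on their medians (adjusted p = 0.00822). It also passed with the mean of all probe sets (adjusted p = 0.00716), with the most variable probe set (adjusted p = 0.00597) and without probe sets of suffix s or x (adjusted p = 0.0206), over a range of 0.00597 to 0.371 in the camera alternatives. The gap between the lists went from −0.46 to −0.48, a difference of −0.028 (exact permutation p = 0.1). Both lists lay near the top of the signal range, with means of 13.2 and 13.7 on shCtrl array 1, whose highest signal was 14.1. Whether such bright signals understate small changes was not tested.

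Of 62 measured factors of ribosome biogenesis, 4 fell, 0 rose and 58 did not pass, with the same counts adjusted over the list alone. The median was −0.15 (adjusted p = 3.20e-04 by camera; adjusted p = 0.371 with an estimated correlation). The members that fell were PES1 and BOP1, partners in a complex of large subunit maturation (−0.48 and −0.40), and POLR1B and POLR1E, subunits of RNA polymerase I (−0.46 and −0.41). The other 5 probe sets of POLR1B lay between −0.47 and 0.02, and in the mean of its probe sets the POLR1B log2 fold change was −0.33, under the fold threshold. The other 2 of POLR1E lay at −0.39 and −0.35. Of 50 mitochondrial ribosomal protein genes, 2 fell, MRPL24 by 0.76 and MRPS9 by 0.40, and the list did not pass (adjusted p = 0.0780 by camera), but it did with arrays centred on their medians (adjusted p = 0.0365) or on housekeeping genes (adjusted p = 0.0373), over a range of 0.0365 to 0.639 in the camera alternatives. The gap between biogenesis factors and mitochondrial ribosomal proteins differed by −0.057 (exact permutation p = 0.1). Of 33 translation factors and other transcripts with a 5′ TOP motif, 0 were called by limma or by the methods' t-test, and 18 had an unadjusted p under 0.05 (median −0.040, adjusted p = 0.193 by camera). That list passed with arrays centred on their medians (adjusted p = 0.0441), with the mean of all probe sets (adjusted p = 0.0359) and with the most variable probe set (adjusted p = 0.0280), over a range of 0.0280 to 0.371 in the camera alternatives. Of 19 aminoacyl-tRNA synthetases, VARS1 fell by 1.05 and HARS1 rose by 0.51, and 17 did not pass (adjusted p = 0.626 by camera).

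Of 19 measured genes of cholesterol synthesis and uptake, 7 fell, 1 rose and 11 did not pass, with the same counts adjusted over the list alone. The median was −0.23 (adjusted p = 0.00148 by camera; adjusted p = 0.371 with an estimated correlation). DHCR7, the last enzyme of one branch of the pathway, fell by 0.80, from 9.03 ± 0.016 to 8.22 ± 0.030 (SD, n = 3). HMGCS1 and MSMO1, an early and a late enzyme, fell by 0.68 and 0.57, and ACAT2 by 0.46. TM7SF2, a sterol reductase, was the member that rose, by 0.51, with its other 4 probe sets between 0.09 and 0.49. Fatty acid synthesis genes went both ways, with 3 of 17 higher and 2 lower: ELOVL6, which lengthens fatty acids, rose by 1.09 and FASN, the fatty acid synthase, fell by 0.80. That list's median was −0.0013, its mean was 0.10, and it did not pass (adjusted p = 0.626 by camera). The gap between the cholesterol and fatty acid lists went from 0.16 ± 0.030 to −0.15 ± 0.0037 (SD, n = 3), a difference of −0.31 (exact permutation p = 0.1).

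Of 30 measured genes of autophagy and the lysosome, 9 rose, 1 fell and 20 did not pass, with the same counts adjusted over the list alone. The median was 0.19 (adjusted p = 0.00883 by camera; adjusted p = 0.430 with an estimated correlation). The lysosomal proteases CTSL and CTSB rose by 0.88 and 0.69, ATP6V0D1, a subunit of the proton pump, by 0.85 (its other 6 probe sets between 0.12 and 0.96), and the membrane protein LAMP1 by 0.61. Of the genes of autophagosome formation, GABARAPL2 rose by 0.46, and ATG3, a conjugating enzyme for it, was the member that fell, by 0.46, with its other 5 probe sets between −0.50 and −0.0021. MAP1LC3B passed on the deposited values, at 0.38 (its other 2 at 0.17 and 0.39), but not with arrays centred on their medians, at 0.32.

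Of 25 measured epithelial genes, 9 rose, 0 fell and 16 did not pass, with the same counts adjusted over the list alone. The list was called higher (adjusted p = 0.0336 by camera; adjusted p = 0.371 with an estimated correlation), with a median of 0.079 and a mean of 0.26. EPCAM, an adhesion molecule, rose by 1.37 from a dim 4.55 ± 0.13 to 5.92 ± 0.073 (SD, n = 3). DSP, a desmosome protein, rose by 0.74 and the claudin CLDN3 by 0.65. The splicing factor ESRP1 rose by 0.61 from a dim 4.44 in shCtrl (0.37 in its other probe set, which was not called). CDH1, dim at 3.93 in shCtrl, stood at 0.08 with its other probe set at −0.03. The call was lost without shRPL35A replicate 3 (adjusted p = 0.0534) and with probe sets of suffix s or x left out (adjusted p = 0.121); over all alternatives its adjusted p ran from 6.99e-05 with fry to 0.371.

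Of 22 measured targets of YAP and TAZ, 6 fell, 1 rose and 15 did not pass, with the same counts adjusted over the list alone. The median was −0.15 (adjusted p = 0.00754 by camera; adjusted p = 0.371 with an estimated correlation). FJX1 fell by 1.07, AMOTL2 by 0.94, GADD45B by 0.73 and the matricellular CCN1 by 0.67. The member above the threshold in the other direction was AMOTL1, at 0.42, which did not pass with arrays centred on their medians, at 0.36, and whose other 3 probe sets lay between −0.18 and 0.47.

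**Figure D3:**
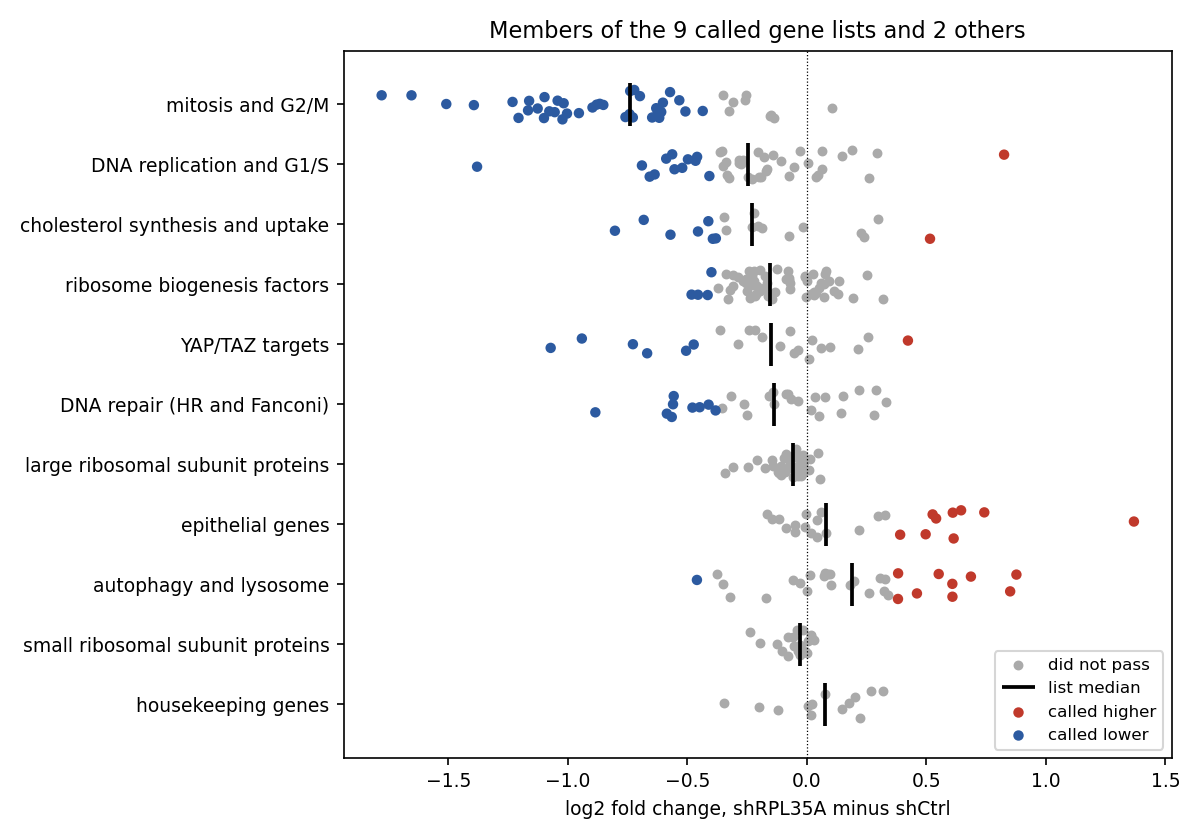
Log2 fold changes (horizontal axis, shRPL35A minus shCtrl) of the measured members of the 9 called lists and of 2 lists that were not called, with 1 point per gene, coloured where the gene was called, and a black line at the list's median. The mitosis list has its median at −0.74, far from the others, and the ribosomal protein lists lie close to zero with 0 called members.

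Targets of p53 and genes of cell death gave no called list. Of 28 p53 target genes, 2 rose and 2 fell (median 0.053, adjusted p = 0.884 by camera). CDKN1A stood at 0.30 and MDM2 at −0.22 (its other 10 probe sets between −0.56 and −0.03), GADD45A fell by 0.57, and TP53INP1 rose by 0.94 in its brightest probe set with its other probe set at −0.06. Of 27 pro-apoptotic genes, 5 rose and 1 fell (adjusted p = 0.555): BIK rose by 1.07 and HRK fell by 0.71. In the methods' t-test the BIK log2 fold change did not pass. Of 11 anti-apoptotic genes, 1 rose and 2 fell (adjusted p = 0.664), among them BIRC5, survivin, which is also in the mitosis list, by 0.61 (its other 11 probe sets between −1.01 and −0.06). CFLAR fell by 0.51 in its brightest probe set, but only 2 of its 8 other probe sets, which ran from −0.55 to 0.23, lay in that direction.

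Stress-response lists did not pass either. Of 32 targets of ATF4, 4 rose and 6 fell (adjusted p = 0.225 by camera): ATF5 rose by 1.00 and the amino acid transporter SLC7A5 fell by 0.99, while ASNS stood at 0.05, which turned to −0.02 with arrays centred on their medians. Of 32 genes of the unfolded protein response, HERPUD1 rose by 0.73 (its other 3 probe sets between 0.28 and 0.71), SEC61A1 and SDF2L1 fell by 0.50 and 0.47, and 29 did not pass (adjusted p = 0.309). Of 21 heat shock genes, HSPB1 and HSPA4 fell by 0.52 and 0.44 and 0 rose (adjusted p = 0.0842). The other 3 probe sets of HSPA4 lay between −0.56 and −0.12. Of 23 NRF2 targets, 3 rose and 0 fell (adjusted p = 0.528), with NQO1 up by 0.55. Of 21 genes of the hypoxia response, 4 rose and 2 fell, with P4HA2 at 0.76 and ADM at −0.73 with its other 2 probe sets at −0.74 and −0.32 (adjusted p = 0.555), and the list's median was −0.063 while its mean was 0.017. Of 27 proteasome subunits, PSMD4 fell by 0.54 and 26 did not pass (adjusted p = 0.692).

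Markers of other cell types gave no called list. Of 14 haematopoietic markers and 10 fibroblast markers, 0 were called by limma or by the methods' t-test, with 2 and 0 at an unadjusted p under 0.05 (adjusted p = 0.699 and 0.874 by camera; for the fibroblast list the test pointed lower and the median was 0.0096). Of 14 lung epithelial lineage markers, FOXA1 fell by 0.42, with its other probe set at −0.17 and their mean at −0.30 under the fold threshold, and 13 did not pass (adjusted p = 0.371). Of 10 embryonic kidney and neuronal markers, LHX1 was higher by 0.43, with its other 2 probe sets at −0.07 and 0.17 (adjusted p = 0.508 for the list); the LHX1 log2 fold change missed the fold threshold without shCtrl replicate 3, at 0.34, and with arrays centred on their medians, at 0.37, and LHX1 did not pass in the methods' t-test. Of 9 genes of neuroendocrine and H1299 lineage, CHGB and ENO2 rose by 0.91 and 0.72 (adjusted p = 0.0805, and adjusted p = 0.0482 or 0.0441 with arrays centred on housekeeping genes or on their medians, over a range of 0.0441 to 0.371 in the camera alternatives). The other 3 probe sets of CHGB lay between 0.05 and 0.26, and with their mean the CHGB log2 fold change, at 0.34, was under the fold threshold. Of 13 housekeeping genes, 0 were called by limma or by the methods' t-test and 10 had an unadjusted p under 0.05 (median 0.074, adjusted p = 0.428). In every list of the report, the counts adjusted over the list alone equalled those over all genes.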

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

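The fit on every probe set was planned, and its split by kind of annotation was chosen after the values were seen. Probe sets that the annotation gives no gene symbol, or several, stood outside the gene comparison and were looked at because they changed between the groups. Of 1947 probe sets without a symbol, 257 changed (13.2%), 126 higher and 131 lower in shRPL35A, against 13.6% of the 43976 probe sets with 1 symbol. Their largest rise was 1.40 and their largest fall −1.41 on the log2 scale. Of 1558 probe sets with several symbols, 161 changed (10.3%), 85 higher and 76 lower. The largest fall among them, −2.53, was in a probe set shared by RPL35A and another gene, one of the brightest on the arrays.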

How the results depend on the processing

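The alternative that left out probe sets of suffix s or x, and the genes checked outside the naming rule, were chosen after the data were seen. Of 1773 alternative values of 99 named genes, 1751 kept their direction and side of the threshold, 21 kept only the direction and 1 reversed: the RRP7A log2 fold change was 0.051 without probe sets of suffix s or x, which leaves a dimmer probe set for the gene. Of 171 alternative values of the 9 called lists, 161 kept direction and call and 10 kept only the direction. Not all of these are separate checks. limma's trend and robust settings do not enter camera, so those values repeat the main ones. The values for an estimated correlation and for fry reuse the main medians, so only the call could change there. The count of changed genes was 6395 (3454 higher, 2941 lower) with every probe set tested by itself, which tests more features; 7530 (4355 higher, 3175 lower) with no fold threshold; and 180 (83 higher, 97 lower) at 2-fold, as those thresholds themselves require. It ran from 2477 to 2573 when each array was left out, and was 2318 by the methods' t-test, 1973 with the mean of all probe sets and 3396 with the most variable probe set. Lists called lower numbered 11 with the mean of all probe sets and 11 with the most variable probe set, against 7; the cause was not tested. Lists called higher numbered 1 without probe sets of suffix s or x, against 2. When each array was left out they ran from 1 (without shRPL35A replicate 3) to 2. Centring on medians or on housekeeping genes added the neuroendocrine and H1299 lineage list to those called higher. Both centrings also added the small subunit and mitochondrial ribosomal protein lists to those called lower, and median centring the translation factor list. The causes were not tested. With an estimated correlation 0 lists were called higher and 1 lower. A higher correlation cannot be the cause for the cholesterol and epithelial lists, whose estimates, 0.0077 and −0.016, lay below the preset 0.01. Nor can it be for the mitosis list, whose estimate was 0.0064 and whose adjusted p by camera still rose from 1.71e-26 to 0.0122. The other lists that lost their call had estimates above the preset, but whether this lowered their calls was not tested. The loss of a call in this setting is therefore not by itself evidence of correlated members. By fry 16 were called higher and 16 lower, since fry does not compare a list with other genes. The replicate block gave 2495 changed genes and changed no list call; deviations of same-numbered arrays correlated at 0.0133, −0.0614 and −0.0649, so the numbers were not taken to pair the arrays. Signal over background limits what can be said from dim probe sets, such as those that stood for EPCAM, ESRP1, CDH1 and RPL27A. APOE, ISG15, CLDN3, HSPB1 and PSMD4 were each read by 1 probe set, of suffix s or x, and have no value once those are left out. With the dimmest genes left out, 2291 of 11689 were called. Lists with under 8 members left in a setting were not tested in it.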

Other observations

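Tests chosen only after the result was seen were the scaling tests of the mitosis and cholesterol genes and the probe set tests of single falling genes. Several further groups moved in part without a called list. Of 40 measured genes of the type I interferon response, 8 rose and 2 fell (adjusted p = 0.193 by camera): ISG15, a ubiquitin-like protein, rose by 1.19 and IFI44 by 0.82 (its other 5 probe sets between 0.32 and 1.02). The members that fell were GBP1, by 0.68 with its other 4 probe sets between −0.89 and −0.34, and IFITM3, by 0.47. Another 3 probe sets that carry several symbols, symbols of that list among them, fell by 1.55, 1.51 and 1.29 and stood outside its test. Of 22 core histone genes, 5 rose and 2 fell (adjusted p = 0.756), with H2BC5 up by 1.20 and H2AC6 by 1.01 in a probe set of suffix s, whose signal is uncertain. Of 28 genes of integrins and focal adhesion, 7 rose and 4 fell (adjusted p = 0.519), and PARVA, an actin-binding adaptor of integrins, fell by 1.06. Of 27 mesenchymal genes, 5 rose and 2 fell (adjusted p = 0.564), among them COL6A1, a chain of collagen VI, up by 1.05 with its other 5 probe sets between 0.10 and 0.68. Of 22 TGF-beta targets, 3 rose and 1 fell (adjusted p = 0.884): TGFBI rose by 0.65 and the ligand gene TGFB1 fell by 0.91. The median of that list was 0.0052 while its test pointed lower.

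Lists of energy metabolism and RNA processing did not pass on the deposited values. Of 20 glycolysis genes, 2 rose and 3 fell (adjusted p = 0.0878 by camera): LDHA, lactate dehydrogenase A, fell by 1.27, with its other 3 probe sets between −1.45 and −1.28. That list passed in the mean of all probe sets (adjusted p = 0.0207) and with the most variable probe set (adjusted p = 0.0209), over a range of 0.0207 to 0.605 in the camera alternatives. Of 41 genes of oxidative phosphorylation, 0 rose and 3 fell (adjusted p = 0.284), among them COX7A2 by 0.40, with its other 4 probe sets between −0.48 and −0.15, and NDUFS3 by 1.07, whose other probe set stood at −0.03. Of 32 spliceosome and SR protein genes, 1 rose and 4 fell, among them SF3B3 by 0.59 and SF3A1 by 0.55. The median of that list was 0.0062 while its mean was −0.054; it did not pass (adjusted p = 0.432), but did with the most variable probe set per gene (adjusted p = 0.0112) and in the mean of all probe sets (adjusted p = 0.0467), over a range of 0.0112 to 0.605 in the camera alternatives. Of 27 NF-kB targets, 4 rose and 1 fell (adjusted p = 0.528), with ICAM1 up by 0.59 and CXCL2 by 0.51. Of 26 immediate early genes, 3 rose and 4 fell (adjusted p = 0.884), with DUSP1, a phosphatase of MAP kinases, at −1.24; the median was 0.0029 and the mean −0.039.

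The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05; 1 of them, the real one, gave as many changed genes, with 2496, and the highest of the others gave 0 by limma and 0 by the methods' t-test. At an unadjusted p under 0.05 with the same fold, the real split gave 2498 and the others from 0 to 3. Every other split has arrays of both groups on each side, so the difference between groups adds to its spread and lowers its calls. These counts therefore do not measure a rate of false calls.

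Mitotic genes were lower together. The tables argue against array scaling, since 1 scale factor per array moves all genes alike and cannot open a gap between lists. The list's median was −0.74 (upper quartile −0.56), against 0.074 for housekeeping genes (lower quartile 0.0054). Centring arrays on housekeeping genes shifts every gene alike, so the list median of −0.80 that it gave is no separate evidence. The tables also argue against probe sets that match several transcripts, since the median over the plain probe sets was −0.72, with 68 of 86 called lower. A smaller share of cells in or near mitosis may account for the fall: a second list of 48 mitotic genes, with no member of the fixed list, had a median of −0.63, and 36 of them fell while 1, ESPL1, rose by 0.48 with its other probe set at −0.06. Of 10000 random lists matched on signal, 100% lay above it, 95% of them from −0.046 to 0.12, but these take no account of correlation between genes. Lower transcription per cell, for which FOXM1 would be a candidate, could lower the second list too. The second list therefore cannot tell these explanations apart, and both stay open, as no cell counts were used here.

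Cholesterol synthesis genes were lower in part: of 19 cholesterol synthesis genes 7 fell, 1 rose and 11 did not pass (adjusted p = 0.00148 by camera; adjusted p = 0.371 with an estimated correlation). Of single genes of sterol export and lipid handling, in no list tested for a rise, APOE rose by 1.43 in its only probe set, of suffix x. ABCA1 and LPCAT3, chosen after their values were seen, rose by 1.28 and 1.28. The other 2 probe sets of ABCA1 stood at 0.15 and 0.65 and the other 4 of LPCAT3 between −0.06 and 0.97. Array scaling is argued against by the gap between this list and housekeeping genes, which 1 scale factor per array cannot open. The cholesterol list's median was −0.23 (upper quartile −0.044), against 0.074 for housekeeping genes (lower quartile 0.0054). Centring on housekeeping genes shifts every gene alike, so the median of −0.29 that it gave is no separate evidence. Sterol excess acting through the nuclear receptor LXR may be a source of the rises of APOE, ABCA1 and LPCAT3 and stays open. The test of LXR targets covers these rises only, not the fall of the cholesterol list. The 16 further LXR targets had a median of −0.015, with 6 above zero, 2 called higher and 1 lower. Of the matched random lists, 34.0% lay below that median, and 95% lay between −0.088 and 0.10. The rise predicted under LXR was thus not seen in these targets as a set. NR1H3 stood at 0.54 and MYLIP, which goes against LXR, at −0.79. APOC1 stood at 0.43 (0.37 and no longer called with arrays centred on their medians), with its other 4 probe sets between −0.30 and 0.47. The prediction written before the test took such a low median as evidence against LXR, without regard to signal or spread. The weighing that leaves LXR open was not in that prediction. By it, 8 of the 16 lay below the median signal of 6.93, and the other 8 spread by 0.21 around −0.00076. A wider rise of lysosomal genes was seen in 34 lysosomal genes outside the fixed list, whose median was 0.28, with 12 higher and 0 lower. Of matched random lists, 95% lay between −0.061 and 0.12, but these take no account of correlation between genes. The fixed autophagy and lysosome list lost its call with an estimated correlation (adjusted p = 0.430 by camera). Whether the lysosomal rise is linked to the fall of cholesterol genes or to the rises of APOE, ABCA1 and LPCAT3 was not tested.

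Of the 12 largest falls among genes at or above the median signal, 8 besides RPL35A lay outside the fixed lists. A faulty probe set could lie behind such a fall. Of these genes, 5 have 10 other probe sets, with a median of −0.70 and 6 of them called lower, but a spread of 0.45 leaves this set open. The prediction written before the test weighed the median alone, by which −0.70 counted against a faulty probe set. The weighing by spread was not in that prediction. Gene by gene, the other probe sets of MYDGF, NHLRC3 and ZIC5, with medians of −1.42, −0.73 and −0.73, argue against 1 faulty probe set as the whole cause, while that of SKP2, at −1.09, has a mean signal of 4.35, under the lower quartile of 4.52, and leaves it open. For RRP7A the median was −0.012. A dim probe set can hide a fall, so lack of a fall was counted only at or above the median signal of all genes, 6.93. Falls were counted above the lower quartile. The other probe sets of RRP7A, between 4.90 and 5.85, all lay under 6.93 and cannot be told apart from unresponsive ones. A brighter probe set shared by RRP7A and another gene, at 7.86, fell by 1.44. Whether it or the brightest RRP7A probe set reads the other gene stays open. GGCT, IL12A and CCNA1 have 1 probe set each and were not tested, and silencing of other transcripts by the hairpin was not tested here.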
